A study of Arabidopsis thaliana with 36 samples.

How the data were processed

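The study measured 3' mRNA tags (QuantSeq, a kit that counts the 3' ends of polyadenylated transcripts) in hypocotyl segments of Arabidopsis thaliana seedlings grown in low light. Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made with the forward version of the kit. The 36 libraries form 12 groups of genotype (WT and ahk3 ahk4), region (basal and medial) and time after wounding (0, 8 and 16 h), with 3 biological replicates each. Nothing in the sources used here says how many seedlings a replicate pooled or on which days replicates were grown.

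The authors deposited 1 table of read counts per library, not normalized, with 32833 gene loci and 5 further lines for reads that were assigned to no gene. HTSeq and DESeq2 are named in the submitters' processing notes without versions. The aligner, the genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed. The lines that name no gene held from 4.594% to 62.196% of a library's reads and were kept out of library sizes and tests. Most of them were reads aligned at more than 1 place, from 2.981% to 60.315% of a library. That share moved with time, genotype and region, in ahk3 ahk4 basal libraries from 44.2% to 60.3% at 0 h and from 3% to 15.1% at 16 h. Its effect on the tests was not measured. Reads outside annotated genes made up from 1.511% to 4.609% of the reads that were assigned to a gene or lay outside genes. The assigned reads of a library ranged from 6136167 to 13557332, with a median of 9744646, and between 18789 and 20519 loci of a library had a read. Gene symbols came from a reference table of the TAIR10.1 assembly, in which 32548 of the loci had an entry and 10804 a symbol of their own. It was used for names and for the order of loci. Replicate libraries differed by more than sampling noise, the lowest chi-square per degree of freedom of a pair being 9.76, so each was counted as 1 sample.

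Each gene was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM normalization factors. Genes were kept by filterByExpr with its default settings and the 12 groups, which left 19819. A single quasi-likelihood model (glmQLFit with robust estimation, glmQLFTest) held 1 mean per group over all 36 libraries, so that all groups shared 1 estimate of the spread per gene with 24 residual degrees of freedom. In it 29 contrasts were tested, 20 between 2 groups and 9 interactions. The contrasts were each time against 0 h per genotype and region, basal against medial per genotype and time, and ahk3 ahk4 against WT per region and time. The interactions were genotype by time per region, region by time in WT, and genotype by region per time. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a contrast. SE values are the log2 fold change divided by the root of the F statistic. CPM are counts scaled to library totals times their TMM factors, and replicates are given as mean ± SD. A fold against a group with no counts used a floor of 3 counts over the group, and a fold against 1 to 3 counts is given with its 95% counting interval. PCR copies are not independent molecules, so these bounds and intervals cover counting error only.

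The comparisons, the tests, 28 gene lists and the rule for named genes were fixed before the data were examined. The lists of hormone genes covered cytokinin receptors, type-A response regulators, cytokinin synthesis and activation, cytokinin breakdown, early auxin response, auxin synthesis and transport, jasmonate, ethylene, abscisic acid and drought, and salicylic acid and camalexin. The lists on growth and stress covered root founder cell and primordium regulators, wound-induced regeneration regulators, reactive oxygen, DNA replication, G2 and mitosis, D-type cyclins, ribosome biogenesis, cell wall loosening, low oxygen, dark and sugar starvation, and the circadian clock. Tissue lists covered photosynthesis, root tissue markers, endodermis and suberin, xylem, phloem, cambium, and shoot epidermis. Their 347 loci were all in the files, and the reference table paired 335 of them with the name used. Each list was tested in each contrast with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with adjustment over the lists of a contrast. The camera test with a correlation estimated from the data and the self-contained fry test were the alternatives. The named genes of a contrast are the 5 highest and 5 lowest log2 fold changes among called genes whose libraries do not overlap between the groups and whose higher group mean is at least 5 CPM. For interactions the overlap condition was left out. The text prints part of these genes. Results of 1 gene that meets this rule are not reported here. Up to 3 members of each list with the smallest adjusted p were added, and AHK3 and AHK4 in every genotype comparison. Chance alone puts 3 libraries wholly above or below 3 others for 10% of genes.

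The model was tested on simulated counts drawn from the fitted means, library sizes and dispersions of the 19819 genes. For the genotype comparison in basal segments at 8 h it called 17 of 100 genes changed 2-fold and 75 of 100 changed 4-fold, with 5 unchanged genes among 97 calls. For the genotype by region interaction at 8 h it called 0 of 100 and 39 of 100 (edgeR's adjusted p), with 1 unchanged gene among 40 calls.

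Other settings tried were RLE size factors, no low-count filter beyond 1 read over all libraries, DESeq2 1.42.0 with its own size factors, a fit of the compared groups alone, an additive block for the replicate number, and leaving out each library of the compared groups in turn. After the data had been seen 2 alternatives were added, the log2 share of reads outside genes as a covariate and a fit without the 4 libraries in which that share was under 2%. Other splits of the compared libraries were refitted on those groups alone, all 10 for a pair of groups and 100 drawn at random for an interaction. Draws of 40 and then of 30 came first. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.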

Results

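Gene expression was measured in hypocotyls of Arabidopsis thaliana seedlings, the stem between root and cotyledons, after the root had been cut off above the root-shoot junction. A hypocotyl cut in this way can form new (adventitious) roots at its base, and the title of the series names the competence for cellular reprogramming in adventitious root formation. Segments of the basal region, next to the wound, and of the medial region were taken at 0, 8 and 16 h after wounding from wild type (WT, accession Col-0) and from ahk3 ahk4, a double mutant of 2 receptors of the plant hormone cytokinin. The 12 groups of genotype, region and time held 3 biological replicates each, 36 libraries of 3' mRNA tags in all. A library held between 6136167 and 13557332 reads assigned to genes, and 19819 genes were tested in each comparison. Levels are mean CPM (counts scaled to TMM-adjusted library totals) ± SD over the 3 libraries of a group. Log2 fold changes stand with their SE and with the adjusted p of edgeR's quasi-likelihood test. For each fixed gene list the members that passed over all genes tested are counted first, the rest not having passed. Next come those that passed when adjusted over the list alone, and the adjusted p of limma's camera test. Where leaving out 1 replicate ended a call, the replicates and the highest adjusted p are given. Where a fit of the compared groups alone ended the call of a gene named here, its log2 fold change moved by at most 0.19. Where a camera call was lost with an estimated correlation between genes, that p follows it. Folds against a group with no counts are lower bounds against a floor of 3 counts over the group, and bounds and the 95% intervals of folds by counts cover counting error only. Where leaving out 1 library of the group with counts lowered such a fold by more than 1.5 times, that fold is given. Unwounded hypocotyls at 8 and 16 h are not among the groups, so time after wounding and hour of sampling move together.

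Transcripts of the 2 mutated receptor genes were lower in every ahk3 ahk4 library than in any WT library. AHK3 lay between 43.9 and 164 CPM in the 18 WT libraries and between 1.33 and 8.71 CPM in the 18 mutant libraries. AHK4 lay between 2.52 and 14.1 CPM in WT and between 0.0986 and 2.2 CPM in the mutant. The third receptor gene, AHK2, ranged from 0.363 to 10.2 CPM in WT and from 0.502 to 6.92 CPM in the mutant. In basal segments at 0 h the mean of AHK3 was 149 ± 13.8 CPM in WT and 6.91 ± 3.05 CPM in the mutant (log2 fold change -4.40 ± 0.37, adjusted p = 8.73e-10). AHK4 was lower in basal segments at 0 h (log2 fold change -4.75 ± 0.63, adjusted p = 6.43e-06) and at 16 h (-2.54 ± 0.57, adjusted p = 0.0108). In medial segments it was lower at 0 h (-2.11 ± 0.54, adjusted p = 0.0148) and 16 h (-2.26 ± 0.56, adjusted p = 0.02). At 8 h its difference did not pass in basal (-2.16 ± 0.53, adjusted p = 0.0648) or medial segments (-1.57 ± 0.54, adjusted p = 0.105), but did by DESeq2 (adjusted p = 0.00341 and 0.0367). Leaving out 1 replicate ended the call of AHK4 in basal segments at 16 h (mutant 2, 0.0552) and in medial segments at 0 h (WT 3, mutant 2, up to 0.109) and 16 h (WT 2, mutant 1 and 3, up to 0.158). In basal segments at 16 h it was -2.16 ± 0.71, adjusted p = 0.191 log2 with the share of reads outside genes as a covariate. The labels give no allele, so whether the counted 3' tags lie outside the disrupted part of either gene is not known here, and tags outside it would check nothing.

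**Figure D1:**
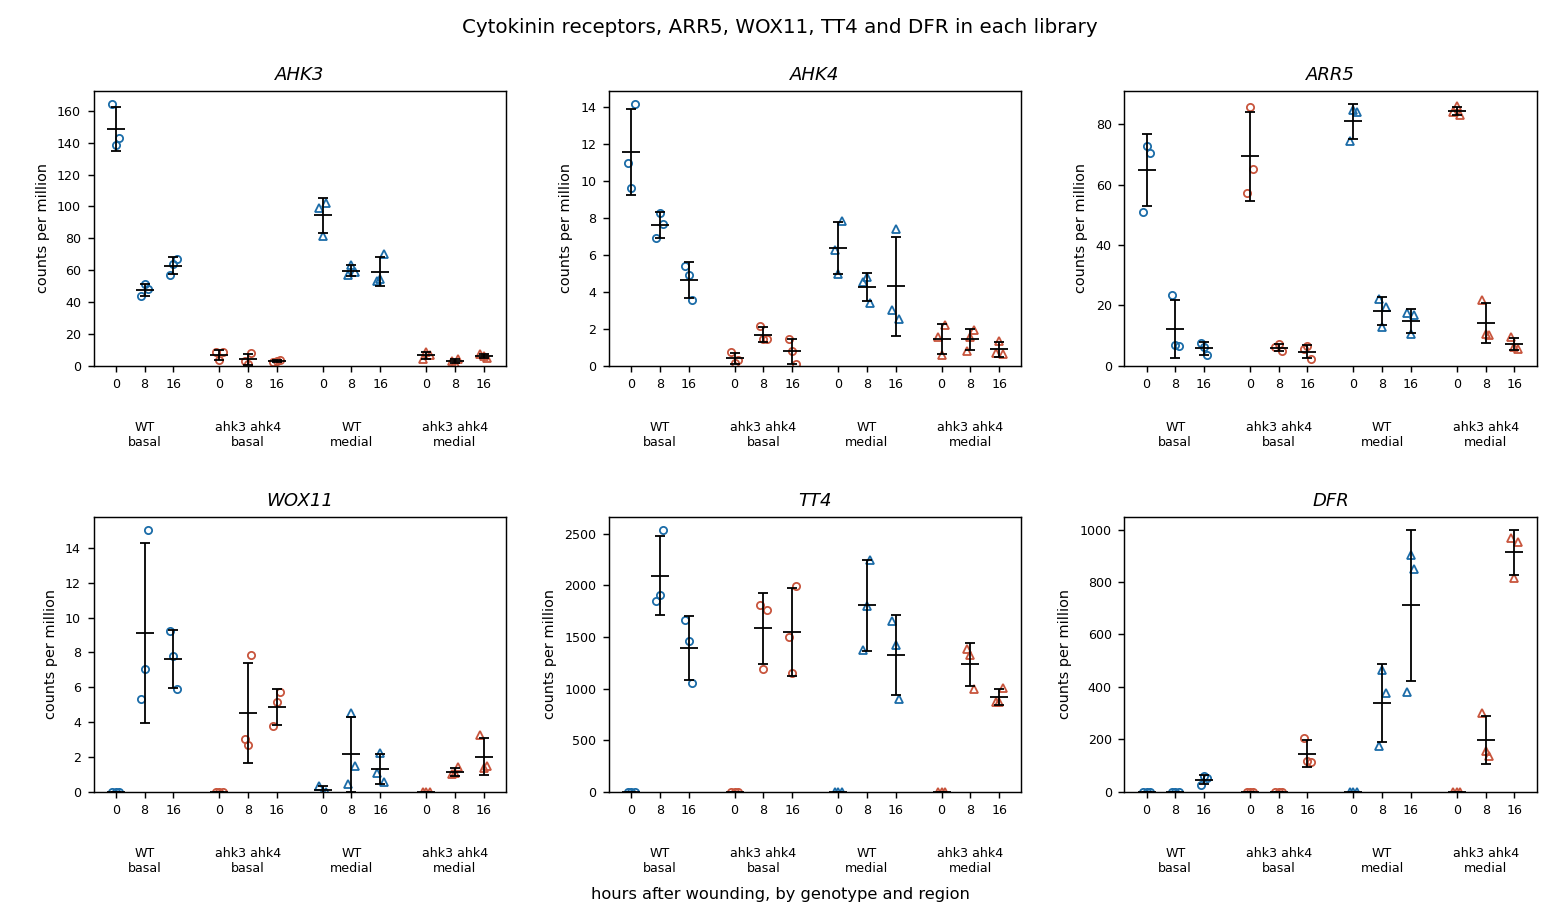
CPM of 6 genes in each of the 36 libraries against hours after wounding, by genotype and region. Open circles are basal and open triangles medial libraries (blue WT, red ahk3 ahk4). The black bar is the mean and its whiskers the SD of 3 libraries. AHK3 is at most 8.71 CPM in ahk3 ahk4 libraries and at least 43.9 CPM in WT. ARR5 is lower at 16 h than at 0 h in both genotypes and regions. DFR at 8 h is 0.162 ± 0.28 CPM in WT basal and 338 ± 148 CPM in WT medial segments.

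In WT basal segments some regulators of root founder cells rose within 8 h of wounding, and the camera test did not call their list. WOX11, a homeobox gene of adventitious root founder cells, went from no counts to 9.12 ± 5.19 CPM (at least 92.4-fold higher, adjusted p = 3.09e-07). GATA23 went from no counts to 4.68 ± 4.27 CPM (at least 47.3-fold higher, 24 without replicate 3, adjusted p = 7.31e-06). LBD16 went from 21.4 ± 3.2 to 68.5 ± 5.31 CPM (log2 fold change 1.68 ± 0.35, adjusted p = 0.000184). Of the root founder cell and primordium regulators 7 of 18 rose and 3 fell (7 and 3 over the list alone, camera adjusted p = 0.598). The ethylene response factor gene ERF108 rose from 7.25 ± 3.47 to 136 ± 16.9 CPM (log2 fold change 4.23 ± 0.33, adjusted p = 1.29e-12). WIND2, another wound-induced regulator, fell (log2 fold change -2.80 ± 0.35, adjusted p = 3.64e-08). Of the wound-induced regeneration regulators 4 of 10 rose and 3 fell (4 and 3 over the list alone, camera adjusted p = 0.257).

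Genes of ribosome production and DNA replication rose in the same segments. FIB2, which encodes the nucleolar protein fibrillarin, went from 21.6 ± 4.09 to 341 ± 48.4 CPM (log2 fold change 3.98 ± 0.30, adjusted p = 4.59e-13). Of the ribosome biogenesis list 7 of 7 rose and 0 fell (7 and 0 over the list alone, camera adjusted p = 1.9e-09). Of the DNA replication genes 9 of 12 rose and 0 fell (11 and 0 over the list alone, camera adjusted p = 0.00591, adjusted p = 0.0766 with an estimated correlation). Among them were MCM4, a subunit of the replicative helicase (log2 fold change 1.87 ± 0.35, adjusted p = 3.43e-05), and the ribonucleotide reductase gene RNR1 (log2 fold change 1.53 ± 0.24, adjusted p = 2.36e-06).

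TT4, which encodes chalcone synthase, the entry enzyme of flavonoid synthesis, had no counts at 0 h and 2095 ± 383 CPM at 8 h (at least 21232-fold higher, adjusted p = 2.26e-20). Among the other genes of the 5 highest fitted folds were ELIP1, an early light-induced protein (13162-fold by counts, 95% interval 2362 to 519937), and MYB111, a flavonol regulator (at least 265-fold). Among the 5 lowest were OCT1 (at least 110-fold lower) and the auxin-induced SAUR24 (at least 71.8-fold) and SAUR20 (at least 63.3-fold), which had no counts at 8 h. SAUR genes have near-identical copies, and how the authors' counting split reads between such copies is uncertain. In all, 4099 genes were higher and 3782 lower at 8 h.

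Photosynthesis and endodermis genes fell in WT basal segments by 8 h. LHCA4, an antenna protein of photosystem I, went from 465 ± 42.7 to 12.4 ± 1.07 CPM (log2 fold change -5.23 ± 0.30, adjusted p = 7.56e-16). Of the photosynthesis list 1 of 20 rose and 17 fell (1 and 17 over the list alone, camera adjusted p = 1.83e-18). The Casparian strip gene CASP1, of the endodermis, went from 712 ± 85.2 to 107 ± 33 CPM (log2 fold change -2.73 ± 0.29, adjusted p = 9.98e-10). ESB1 changed by -2.93 ± 0.33 log2. Of the endodermis and suberin list 0 of 14 rose and 10 fell (0 and 12 over the list alone, camera adjusted p = 1.34e-06). Of the dark and sugar starvation genes 0 of 8 rose and 6 fell (0 and 6 over the list alone, camera adjusted p = 0.00231, adjusted p = 0.0766 with an estimated correlation). Of the phloem genes 0 of 7 rose and 4 fell (0 and 4 over the list alone, camera adjusted p = 0.0168, adjusted p = 0.128 with an estimated correlation). Of the circadian clock genes 3 of 13 rose and 7 fell (3 and 7 over the list alone, camera adjusted p = 0.0359, adjusted p = 0.0907 with an estimated correlation). LHY changed by -3.64 ± 0.33 and PRR7 by -3.82 ± 0.42 log2. The adjusted p of the list was 0.0679 with the share of reads outside genes as a covariate. Early auxin response genes went both ways, with GH3.5 (-2.71 ± 0.37 log2) and IAA3 (-1.63 ± 0.23) down and IAA5 up (3.44 ± 0.62). In that list 2 of 19 rose and 8 fell (2 and 8 over the list alone, camera adjusted p = 0.453). Its median was -0.24 and its mean 0.02 log2.

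By 16 h type-A response regulators, the primary transcripts induced by cytokinin, had fallen in WT basal segments. ARR5 went from 64.8 ± 11.9 to 5.79 ± 2.15 CPM (log2 fold change -3.48 ± 0.41, adjusted p = 1.39e-08). ARR4 changed by -1.29 ± 0.22 and ARR6 by -2.14 ± 0.46 log2. In the list 0 of 8 rose and 5 fell (0 and 6 over the list alone, camera adjusted p = 0.00693, adjusted p = 0.132 with an estimated correlation). PUCHI, a regulator of root primordia, went from no counts to 3.92 ± 0.96 CPM (at least 39.7-fold higher, adjusted p = 8.85e-05). Of the root founder list 9 of 18 rose and 2 fell (9 and 3 over the list alone, camera adjusted p = 0.166). Of the DNA replication genes 9 of 12 rose and 0 fell (11 and 0 over the list alone, camera adjusted p = 0.00282). Of the abscisic acid and drought list 0 of 10 rose and 8 fell (0 and 8 over the list alone, camera adjusted p = 0.00282). Of the endodermis list 0 of 14 rose and 12 fell (0 and 12 over the list alone, camera adjusted p = 1.97e-08). Among the 5 highest fitted folds at 16 h were those of TT4 (at least 14093-fold), GSTF12 (at least 556-fold) and MYB90 (at least 166-fold). Among the 5 lowest were those of AIR1 (at least 160-fold lower, 100 without replicate 1) and the expansin gene EXPA8 (at least 107-fold, 61.3 without replicate 1). At 16 h 3954 genes were higher and 3529 lower.

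The other fixed lists gave no camera call in WT basal segments at 8 h. Members up and down, with those adjusted over the list alone in parentheses, were 0 and 2 of 3 (0 and 2) for cytokinin receptors and 0 and 1 of 8 (0 and 1) for type-A response regulators. They were 1 and 2 of 11 (1 and 2) for cytokinin synthesis and activation, 2 and 0 of 5 (2 and 0) for cytokinin breakdown and 1 and 5 of 14 (1 and 5) for auxin synthesis and transport. They were 2 and 6 of 22 (2 and 6) for jasmonate, 4 and 1 of 12 (4 and 1) for ethylene, 2 and 5 of 10 (2 and 6) for abscisic acid and drought and 0 and 2 of 7 (0 and 2) for salicylic acid and camalexin. For stress they were 1 and 1 of 14 (1 and 1) for reactive oxygen and 3 and 1 of 9 (3 and 2) for low oxygen. For growth they were 0 and 2 of 7 (0 and 2) for D-type cyclins, 0 and 5 of 16 (0 and 4) for G2 and mitosis and 3 and 4 of 10 (3 and 4) for cell wall loosening. For tissues they were 1 and 1 of 4 (2 and 1) for root tissue markers, 0 and 1 of 10 (0 and 1) for xylem, 0 and 1 of 4 (0 and 1) for cambium and 1 and 4 of 9 (1 and 4) for shoot epidermis.

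In WT medial segments, away from the wound, early auxin response genes fell. IAA19 went from 46.7 ± 20.4 to 3.08 ± 0.573 CPM at 8 h (log2 fold change -3.92 ± 0.59, adjusted p = 2.2e-06). GH3.5, which conjugates auxin to amino acids, went from 53.1 ± 3.34 to 2.52 ± 0.942 CPM (log2 fold change -4.38 ± 0.40, adjusted p = 6.84e-11). Of this list at 8 h 0 of 19 rose and 14 fell (0 and 16 over the list alone, camera adjusted p = 8.16e-07). At 16 h 0 of 19 rose and 13 fell (0 and 15 over the list alone, camera adjusted p = 3.64e-08). Of the cell wall loosening genes at 8 h 2 of 10 rose and 6 fell (2 and 7 over the list alone, camera adjusted p = 0.002, adjusted p = 0.0661 with an estimated correlation). XTH19 fell from 473 ± 115 to 17.3 ± 4.44 CPM (-4.78 ± 0.48 log2) and XTH20 rose (2.33 ± 0.30). Of the ribosome biogenesis genes at 8 h 7 of 7 rose and 0 fell (7 and 0 over the list alone, camera adjusted p = 1.17e-08). Of the DNA replication genes 10 of 12 rose and 0 fell (10 and 0 over the list alone, camera adjusted p = 0.00165). Of the dark and sugar starvation genes 0 of 8 rose and 7 fell (0 and 8 over the list alone, camera adjusted p = 6.25e-05).

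DFR, a late enzyme of anthocyanin synthesis, went in WT medial segments from no counts to 338 ± 148 CPM at 8 h (at least 2762-fold higher, adjusted p = 2.7e-10) and 710.5 ± 288 CPM at 16 h (at least 5803-fold). TT4 (44496-fold by counts, 95% interval 7986 to 1757542), GSTF12 (at least 1190-fold), the anthocyanin regulator MYB90 (at least 995-fold) and GPT2 (at least 338-fold) were with DFR the 5 highest fitted folds at 8 h. TIP2;3 (at least 1399-fold lower, 516 without replicate 2), the starvation gene ASN1 (at least 1021-fold) and AIR1 (at least 363-fold, 20.7 without replicate 2, adjusted p = 0.194 in a fit of the compared groups alone) were among the lowest. At 16 h photosynthesis genes went both ways. RBCS1A rose from 208 ± 45.3 to 2982 ± 153 CPM (log2 fold change 3.84 ± 0.28, adjusted p = 2.68e-13) and LHCB1.4 fell (-4.46 ± 0.37 log2), both from families with near-identical copies. Of the photosynthesis list 8 of 20 rose and 3 fell (9 and 3 over the list alone, camera adjusted p = 0.066). Salicylic acid synthesis and signalling genes rose by 16 h, ICS1 by 2.46 ± 0.38 and PAD4 by 2.19 ± 0.47 log2. Of that list 5 of 7 rose and 0 fell (5 and 0 over the list alone, camera adjusted p = 0.0173, adjusted p = 0.102 with an estimated correlation). Of the type-A response regulators at 16 h 0 of 8 rose and 5 fell (0 and 6 over the list alone, camera adjusted p = 0.016, adjusted p = 0.143 with an estimated correlation). Counts were 4075 higher and 3845 lower at 8 h, and 4229 and 3573 at 16 h.

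In ahk3 ahk4 basal segments early auxin response genes went both ways by 8 h. IAA14 rose from 0.993 ± 0.766 to 28.2 ± 11.5 CPM (log2 fold change 4.73 ± 0.56, adjusted p = 2.29e-08). IAA5 rose (212-fold by counts, 95% interval 58.3 to 1751), as did GH3.6 (1.56 ± 0.27 log2). Of the list 9 of 19 rose and 3 fell (9 and 3 over the list alone, camera adjusted p = 0.369). Of the ribosome biogenesis genes 7 of 7 rose and 0 fell (7 and 0 over the list alone, camera adjusted p = 5.59e-06). Of the DNA replication genes 9 of 12 rose and 0 fell (9 and 0 over the list alone, camera adjusted p = 0.00184, adjusted p = 0.0555 with an estimated correlation). Of the endodermis genes 0 of 14 rose and 9 fell (0 and 9 over the list alone, camera adjusted p = 5.59e-06). ERF108 (3.05 ± 0.31 log2) and ERF114 (3.25 ± 0.50) rose as well. AT5G19890 (at least 600-fold) was among the highest at 8 h. DVL21 (at least 61.8-fold lower), MBP1 (at least 59.6-fold, 34.5 without replicate 1, adjusted p = 0.349 by DESeq2) and UMAMIT29 (at least 57.9-fold) were the lowest.

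At 16 h type-A response regulators were down in the mutant as well. ARR5 went from 69.4 ± 14.7 to 4.72 ± 2.18 CPM in basal segments (log2 fold change -3.87 ± 0.41, adjusted p = 1.65e-09). Of the list 0 of 8 rose and 6 fell (0 and 6 over the list alone, camera adjusted p = 0.00429, adjusted p = 0.103 with an estimated correlation). With the share of reads outside genes as a covariate that p was 0.0663. Of the G2 and mitosis genes 9 of 16 rose and 0 fell (10 and 0 over the list alone, camera adjusted p = 0.11). The cyclin CYCB1;3 changed by 1.68 ± 0.38 and the Aurora kinase AUR1 by 1.33 ± 0.38 log2. With that covariate they changed by 1.33 ± 0.54, adjusted p = 0.0598 and 1.3 ± 0.54, adjusted p = 0.0679. GSTF12 (at least 1556-fold), DFR (at least 1247-fold) and LDOX (at least 538-fold) rose. The wax synthase gene WSD1 fell (at least 117-fold). Counts were 4620 higher and 3898 lower at 8 h, and 4905 and 4398 at 16 h. In 2 of the 3 mutant basal libraries at 16 h under 2% of reads lay outside genes. Leaving out the 4 such libraries of the series keeps 1 library in that group, so no count of that fit is given.

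In ahk3 ahk4 medial segments ARR5 fell by 8 h from 84.4 ± 1.42 to 14.2 ± 6.59 CPM (log2 fold change -2.57 ± 0.38, adjusted p = 1.62e-06). Of the type-A list 0 of 8 rose and 4 fell (0 and 4 over the list alone, camera adjusted p = 0.0177, adjusted p = 0.254 with an estimated correlation). ICS1, which starts salicylic acid synthesis, rose by 16 h from 1.47 ± 0.234 to 30.5 ± 5.21 CPM (log2 fold change 4.36 ± 0.41, adjusted p = 8.88e-11). WRKY70 changed by 5.18 ± 0.72 log2. Of the salicylic acid and camalexin list 6 of 7 rose and 0 fell (6 and 0 over the list alone, camera adjusted p = 0.00141, adjusted p = 0.0597 with an estimated correlation). Of the early auxin response genes at 16 h 1 of 19 rose and 10 fell (1 and 10 over the list alone, camera adjusted p = 0.00183, adjusted p = 0.0597 with an estimated correlation). The genes with the highest folds at 8 h included DFR (at least 1930-fold) and GPT2 (at least 950-fold, 604 without replicate 1), and those at 16 h LDOX (at least 2889-fold). TIP2;3 (at least 1021-fold lower) and OCT1 (at least 286-fold) were among the lowest at 8 h. Counts were 4098 higher and 3425 lower at 8 h, and 3814 and 3181 at 16 h.

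Basal and medial segments of WT already differed at 0 h. The gene FACT was higher in basal segments (log2 fold change 5.59 ± 1.07, adjusted p = 0.000911), as was VSP2, a jasmonate-responsive storage protein (4.41 ± 0.85 log2). GER3 (at least 167-fold lower) and the epidermis gene PDF1 (at least 133-fold) were lower. Early auxin genes were lower in basal segments. IAA14 stood at 9.34 ± 4.66 against 51.4 ± 8.03 CPM (log2 fold change -2.46 ± 0.46, adjusted p = 0.000266). Of that list 0 of 19 were higher and 9 were lower (0 and 9 over the list alone, camera adjusted p = 3.87e-06). Of the shoot epidermis genes 0 of 9 were higher and 6 were lower (0 and 6 over the list alone, camera adjusted p = 8.11e-07). Of the photosynthesis genes 0 of 20 were higher and 12 were lower (0 and 18 over the list alone, camera adjusted p = 1.36e-13, adjusted p = 0.0634 with an estimated correlation). Of the cell wall loosening genes 2 of 10 were higher and 5 were lower (2 and 6 over the list alone, camera adjusted p = 0.00161, adjusted p = 0.0688 with an estimated correlation). Of the jasmonate list 6 of 22 were higher and 0 were lower (9 and 0 over the list alone, camera adjusted p = 0.000346, adjusted p = 0.158 with an estimated correlation). In all, 1148 genes were higher and 1329 lower in basal segments.

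At 8 h the WT basal segments had more of the wound-induced regulators. ERF108 stood at 136 ± 16.9 against 42.9 ± 10.1 CPM (log2 fold change 1.67 ± 0.29, adjusted p = 7.65e-05). WIND3 stood at 36.5 ± 9.95 against 8.75 ± 4.99 CPM (2.06 ± 0.37 log2) and ERF114 at 77.4 ± 7.43 against 12.7 ± 2.06 CPM (2.60 ± 0.48). Of the list 5 of 10 were higher and 0 were lower (5 and 0 over the list alone, camera adjusted p = 0.000344). The anthocyanin genes UF3GT (at least 225-fold lower) and DFR (log2 fold change -10.88 ± 0.83, adjusted p = 4.65e-09) were lower in basal segments. Of the photosynthesis genes 0 of 20 were higher and 19 were lower (0 and 19 over the list alone, camera adjusted p = 3.92e-49). The phosphate transporter gene PHT1;1 stood at 194 ± 100.5 against 5.99 ± 4.72 CPM (log2 fold change 5.00 ± 1.23, adjusted p = 0.00605). Of the root tissue markers 2 of 4 were higher and 0 were lower (2 and 0 over the list alone, camera adjusted p = 0.0109). The counts were 1354 higher and 1446 lower.

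At 16 h genes of the endodermis and suberin differed both ways between basal and medial segments of WT. The Casparian strip gene ESB1 stood at 79.3 ± 19.6 against 1149 ± 122 CPM (log2 fold change -3.86 ± 0.35, adjusted p = 9.03e-10). CASP1 differed by -3.11 ± 0.29 log2. Of the endodermis and suberin list 4 of 14 were higher and 7 were lower (6 and 7 over the list alone, camera adjusted p = 4.54e-05). WIND3 was higher in basal segments (log2 fold change 2.27 ± 0.38, adjusted p = 3.4e-05). Of the wound-induced regulators 3 of 10 were higher and 0 were lower (6 and 0 over the list alone, camera adjusted p = 0.00343). Of the photosynthesis genes 0 of 20 were higher and 20 were lower (0 and 20 over the list alone, camera adjusted p = 2.44e-26). The peptide gene RGF6 was among the lowest (422-fold by counts, 95% interval 75.3 to 16687). The counts were 1959 higher and 2157 lower.

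In ahk3 ahk4 the regions differed at 0 h in FACT (at least 232-fold higher in basal segments) and GER3 (at least 400-fold lower). Of the early auxin genes 0 of 19 were higher and 9 were lower (1 and 10 over the list alone, camera adjusted p = 2.53e-06). Of the salicylic acid and camalexin list 5 of 7 were higher and 0 were lower (5 and 1 over the list alone, camera adjusted p = 0.000137). At 8 h CASP1 stood at 26.1 ± 8.7 CPM in basal against 209 ± 19.1 CPM in medial segments (log2 fold change -3.00 ± 0.29, adjusted p = 3.02e-09). Of the endodermis genes 5 of 14 were higher and 7 were lower (5 and 7 over the list alone, camera adjusted p = 9.52e-05). Their median was -0.87 and their mean 0.44 log2. Of the wound-induced regulators at 8 h 3 of 10 were higher and 0 were lower (3 and 0 over the list alone, camera adjusted p = 0.00203). Of the root tissue markers 3 of 4 were higher and 0 were lower (4 and 0 over the list alone, camera adjusted p = 0.000267). LDOX, an enzyme of anthocyanin synthesis, was lower in basal segments at 8 h (2944-fold by counts, 95% interval 528 to 116337). At 16 h PHI-1 (log2 fold change 7.02 ± 1.28, adjusted p = 0.000186) and PHT1;1 (5.67 ± 1.27 log2) were higher in basal segments. There CASP5 (-8.05 ± 0.92) and EXPA11 (624-fold by counts, 95% interval 112 to 24687) were lower. Higher and lower counts were 1020 and 1432 at 0 h, 1166 and 1456 at 8 h, and 2682 and 2585 at 16 h. Without the 4 libraries with under 2% of reads outside genes the total at 16 h was 2197 in place of 5267. At 8 h it was 1197 in a fit of those groups alone.

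Whether WT regions differed in their change over time was tested as a region by time interaction. IAA14 went from 9.34 ± 4.66 to 51.1 ± 2.01 CPM in basal and from 51.4 ± 8.03 to 11.2 ± 3.78 CPM in medial segments (interaction log2 fold change 4.65 ± 0.64, adjusted p = 1.69e-05). IAA5 went from 3.57 ± 1.37 to 39.1 ± 5.76 and from 16.6 ± 1.56 to 2.69 ± 2.21 CPM (6.08 ± 0.87 log2). Of the early auxin list at 8 h 7 of 19 had a positive interaction and 0 a negative one (9 and 0 over the list alone, camera adjusted p = 2.42e-09). At 16 h 7 of 19 had a positive interaction and 0 a negative one (8 and 0 over the list alone, camera adjusted p = 3.32e-06). ESB1 went from 942 ± 69.7 to 79.3 ± 19.6 CPM in basal and from 799 ± 227 to 1149 ± 122 CPM in medial segments (interaction log2 fold change -4.09 ± 0.46, adjusted p = 2.09e-07). Of the endodermis list at 16 h 0 of 14 had a positive interaction and 7 a negative one (0 and 8 over the list alone, camera adjusted p = 1.89e-09). Of the wound-induced regulators at 8 h 4 of 10 had a positive interaction and 0 a negative one (5 and 0 over the list alone, camera adjusted p = 0.0318, adjusted p = 0.0824 with an estimated correlation). Of the photosynthesis genes 0 of 20 had a positive interaction and 12 a negative one (1 and 15 over the list alone, camera adjusted p = 1.53e-14, adjusted p = 0.0733 with an estimated correlation). ACS8, an ethylene synthesis gene (10.37 ± 2.13 log2), and the peptide gene CLE14 (9.42 ± 1.63) had the highest interactions at 8 h, and DFR (-14.40 ± 3.16) the lowest. These values depend on the prior count where a group has next to no counts. The call of DFR ended with 1 library left out (basal 0 h 1, 1 as its adjusted p). The interaction passed for 632 genes upward and 583 downward at 8 h, and 920 and 1083 at 16 h.

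**Figure D2:**
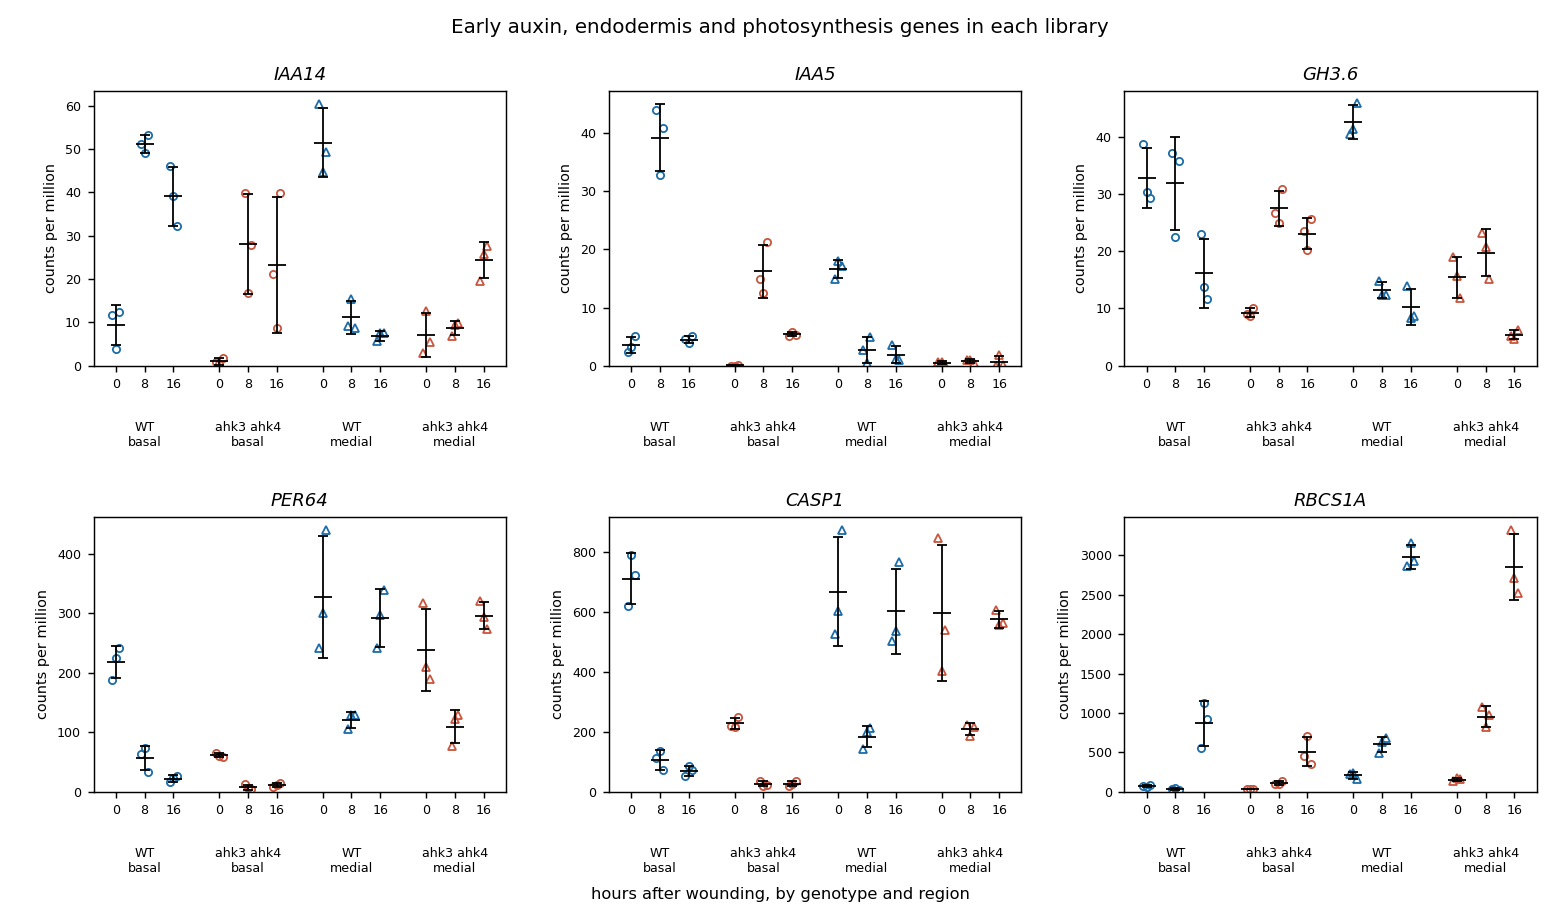
CPM of 6 genes in each of the 36 libraries against hours after wounding, by genotype and region. Open circles are basal and open triangles medial libraries (blue WT, red ahk3 ahk4). The black bar is the mean and its whiskers the SD of 3 libraries. IAA14 at 0 h is 7.07 ± 5 CPM in ahk3 ahk4 against 51.4 ± 8.03 CPM in WT medial segments. PER64 in basal segments at 8 h is 7.56 ± 4.07 CPM in ahk3 ahk4 against 56.6 ± 20.6 CPM in WT.

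At 0 h ahk3 ahk4 segments had less of the early auxin response transcripts than WT. In basal segments the share of reads aligned at more than 1 place, for which nothing was adjusted, also differed (44.2% to 60.3% in mutant and 34.9% to 40.5% in WT libraries). In basal segments IAA1 stood at 6.23 ± 1.53 against 38 ± 12 CPM (log2 fold change -2.61 ± 0.36, adjusted p = 1.19e-05). GH3.6 stood at 9.29 ± 0.767 against 32.7 ± 5.18 CPM (-1.81 ± 0.27 log2) and IAA17 at 178 ± 19.4 against 608 ± 51.6 CPM (-1.77 ± 0.27). Of the list 0 of 19 were higher and 11 were lower (0 and 13 over the list alone, camera adjusted p = 1.28e-15). In medial segments IAA5 (log2 fold change -5.07 ± 0.74, adjusted p = 3.05e-05), IAA14 (-2.86 ± 0.47 log2) and GH3.6 (-1.46 ± 0.26) were lower. Of the list 0 of 19 were higher and 13 were lower (0 and 13 over the list alone, camera adjusted p = 2.38e-12). The expansin gene EXPA8 stood at 0.203 ± 0.352 against 10.7 ± 8.01 CPM in basal segments (log2 fold change -5.47 ± 0.79, adjusted p = 7.55e-05). Of the cell wall loosening list 0 of 10 were higher and 3 were lower (0 and 5 over the list alone, camera adjusted p = 2.07e-07) in basal segments. In medial segments 0 of 10 were higher and 6 were lower (0 and 7 over the list alone, camera adjusted p = 7.78e-08).

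CASP1 (log2 fold change -1.64 ± 0.28, adjusted p = 0.000223) and ACL5, which acts in xylem differentiation (log2 fold change -1.57 ± 0.28, adjusted p = 0.000433), were lower in mutant basal segments at 0 h. Of the endodermis list 0 of 14 were higher and 5 were lower (0 and 7 over the list alone, camera adjusted p = 1.13e-10). Of the xylem list 0 of 10 were higher and 5 were lower (0 and 8 over the list alone, camera adjusted p = 2.5e-09). Of the type-A response regulators at 0 h 0 of 8 were higher and 0 were lower (0 and 0 over the list alone, camera adjusted p = 0.548) in basal segments. In medial ones 0 of 8 were higher and 0 were lower (0 and 0 over the list alone, camera adjusted p = 0.85). At an unadjusted p under 0.05 edgeR had 0 of the 8 higher and 2 lower in basal segments (DESeq2 called 0 and 0 at an adjusted p under 0.05). By the same count edgeR had 1 of the 8 higher and 2 lower in medial segments (DESeq2 called 0 and 0 at an adjusted p under 0.05). The 5 lowest fitted folds in basal segments were those of AT5G19890 (at least 124-fold lower, 16.4 without replicate 2), RGF6 (651-fold by counts, 95% interval 117 to 25752), AT2G21045 (at least 44.5-fold, 8.5 without replicate 2), SAUR20 (205-fold by counts, 95% interval 36.5 to 8149) and SAUR24 (76.4-fold by counts, 95% interval 25.9 to 373). Among the 5 highest was that of AT1G64795 (at least 105-fold higher). In medial segments AT1G64795 (at least 41.8-fold), GSTU25 (86.2-fold by counts, 95% interval 23.6 to 716) and the kinase gene FRK1 (4.60 ± 0.66 log2) were among the 5 highest. AIR1 was the lowest (at least 356-fold lower, 20.3 without replicate 2). In fits of the compared groups alone the adjusted p was 0.464 for AIR1, and 0.405 for AT5G19890 and 0.0531 for AT2G21045 in basal segments. Counts were 167 higher and 443 lower in basal and 518 and 626 in medial segments. With 1 of the compared libraries left out, totals lay between 342 (without ahk3 ahk4 basal 0 h replicate 1) and 465 in basal and between 560 (without ahk3 ahk4 medial 0 h replicate 2) and 916 in medial segments. Replicates whose removal ended a call, and the highest adjusted p, were AT5G19890 (WT 2, mutant 1, 2 and 3, up to 0.375) and AT2G21045 (WT 2, mutant 1, 2 and 3, up to 0.218) in basal segments.

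At 8 h, as at 0 h, genes of the endodermis were lower in basal segments of ahk3 ahk4 than of WT. The Casparian strip peroxidase gene PER64 stood at 7.56 ± 4.07 against 56.6 ± 20.6 CPM (log2 fold change -2.89 ± 0.32, adjusted p = 6.21e-07). CASP2 (-2.75 ± 0.45 log2), CASP1 (-2.03 ± 0.28) and CASP4 (-2.65 ± 0.43) were lower too. Of the endodermis list 0 of 14 were higher and 5 were lower (0 and 5 over the list alone, camera adjusted p = 4.68e-15). RBCS1A stood at 113 ± 24.4 against 35.6 ± 10.1 CPM (log2 fold change 1.67 ± 0.26, adjusted p = 0.000387). RBCS1B differed by 2.28 ± 0.44 and GAPB by 1.98 ± 0.37 log2, and RBCS genes are near-identical copies. Of the photosynthesis list 3 of 20 were higher and 0 were lower (10 and 0 over the list alone, camera adjusted p = 6.68e-17). Of the type-A response regulators 0 of 8 were higher and 0 were lower (0 and 4 over the list alone, camera adjusted p = 7.9e-08), and the list lay lower in the mutant. At an unadjusted p under 0.05 edgeR had 0 of the 8 higher and 5 lower in basal segments (DESeq2 called 0 and 1 at an adjusted p under 0.05). AT1G27565 (at least 93.4-fold higher), AT1G64795 (at least 46.2-fold) and AT5G42760 (2.59 ± 0.53 log2) had the highest folds, and MRD1 the lowest (log2 fold change -3.84 ± 0.61, adjusted p = 0.00124). In all 32 genes were higher and 26 lower. Between 35 (without WT basal 8 h replicate 3) and 61 passed with 1 of the 6 libraries left out. Leaving out 1 replicate ended the calls of AT5G42760 (WT 1, 2 and 3, mutant 2, up to 0.128), RBCS1B (WT 1, 2 and 3, up to 0.0952) and GAPB (WT 3, 0.0642).

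In medial segments at 8 h ARR4 was lower in the mutant (log2 fold change -0.87 ± 0.21, adjusted p = 0.0234). ARR6 stood at 4.35 ± 3 against 12.9 ± 1.98 CPM without passing (log2 fold change -1.57 ± 0.46, adjusted p = 0.0579). It passed by DESeq2 (adjusted p = 0.0169) and without mutant replicate 2 (0.0443) or 3 (0.0328). Of the type-A list 0 of 8 were higher and 1 were lower (0 and 4 over the list alone, camera adjusted p = 4.3e-05). XPL1, a gene of phosphocholine synthesis, stood at 172 ± 48.4 against 1021 ± 333 CPM (log2 fold change -2.57 ± 0.53, adjusted p = 0.0105). MRD1 differed by -4.83 ± 0.64, AT3G01345 by -2.37 ± 0.44 and AT3G28580 by -2.15 ± 0.51 log2. AT1G27565 (388-fold by counts, 95% interval 69.3 to 15373) and AT1G22630 (4.18 ± 0.87 log2) were among the highest. In all 376 genes were higher and 72 lower. That total was 3 in a fit of these 6 libraries alone and between 55 (without WT medial 8 h replicate 3) and 1440 (without ahk3 ahk4 medial 8 h replicate 3) with 1 of them left out. That fit ended the calls, and not the folds, of the genes named here but MRD1 and AT1G27565, with adjusted p from 0.0674 for XPL1 to 0.424 for ARR4. The total was 126 without the 4 libraries with under 2% of reads outside genes, 1 of which is replicate 1 of this mutant group. Leaving out 1 replicate ended the calls of ARR4 (WT 2 and 3, mutant 1, up to 0.134), XPL1 (WT 3, mutant 1, up to 0.0681), AT3G28580 (WT 2 and 3, mutant 1, up to 0.155) and AT1G22630 (WT 2 and 3, up to 0.0753).

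At 16 h MRD1 was lower in the mutant in basal (log2 fold change -5.27 ± 0.67, adjusted p = 6e-05) and medial segments (log2 fold change -5.24 ± 0.66, adjusted p = 9.8e-05). In basal segments CESA8 (log2 fold change -2.05 ± 0.36, adjusted p = 0.00115) and CESA4 (-1.88 ± 0.37 log2), cellulose synthases of the secondary wall, were lower. Of the xylem list 0 of 10 were higher and 3 were lower (0 and 4 over the list alone, camera adjusted p = 0.000402, adjusted p = 0.0951 with an estimated correlation). In these segments organelle reads (0.25% to 0.94% in mutant, 1.34% to 1.35% in WT libraries), reads aligned at more than 1 place (3% to 15.1% and 23% to 27.8%) and reads outside genes (1.51% to 2.64% and 2.98% to 3.3%) separate the genotypes too. CASP1 was lower (log2 fold change -1.37 ± 0.28, adjusted p = 0.00537). Of the endodermis list 0 of 14 were higher and 3 were lower (1 and 6 over the list alone, camera adjusted p = 0.00098, adjusted p = 0.127 with an estimated correlation). AT1G27565 (at least 132-fold higher, 84.1 without replicate 1), GPT2 (3.17 ± 0.58 log2) and AGP5 (3.14 ± 0.57) were among the 5 highest folds in basal segments. In medial segments ACL5 (log2 fold change -1.36 ± 0.28, adjusted p = 0.00669), GRP9 (-3.54 ± 0.85 log2) and AT2G05510 (-5.63 ± 1.04) were lower. Among the highest folds there were those of the plastid genes ATCG00250 (182-fold by counts, 95% interval 32.2 to 7249) and ATCG00140 (186-fold by counts, 95% interval 32.9 to 7393). Organelle reads separate these 2 groups too (2.18% to 3.02% in mutant, 1.03% to 1.79% in WT libraries). So do reads outside genes (3.56% to 4.33%, 2.06% to 3.02%) and reads aligned at more than 1 place (19.9% to 30.7%, 7.9% to 17.4%). The plastid folds move with these traits. Counts were 456 higher and 526 lower in basal and 299 and 359 in medial segments. In basal segments 106 genes passed with the share of reads outside genes as a covariate. Between 73 (without ahk3 ahk4 basal 16 h replicate 1) and 2412 (without ahk3 ahk4 basal 16 h replicate 3) passed with 1 library left out, and in medial segments between 177 (without ahk3 ahk4 medial 16 h replicate 3) and 453. With that covariate CESA4 (-1.73 ± 0.44, adjusted p = 0.0646) and AGP5 (1.78 ± 0.52, adjusted p = 0.128) lost their call in basal segments, CESA4 with a fold near the one without it. In medial ones ACL5 (-0.87 ± 0.29, adjusted p = 0.101), ATCG00250 (4.83 ± 1.36, adjusted p = 0.0526) and ATCG00140 (5.19 ± 1.64, adjusted p = 0.086) lost it. The adjusted p of GRP9 was 0.222 in those groups alone. Leaving out the 4 libraries with under 2% of reads outside genes keeps 1 mutant library in basal segments. There the log2 fold changes were then -0.98 for CASP1, -1.97 for CESA8, 2.77 for GPT2, -2.48 for CESA4 and 1.82 for AGP5. Leaving out 1 replicate ended the call of CASP1 (WT 2, mutant 1, up to 0.0725) in basal segments. In medial segments it ended those of ACL5 (WT 3, 0.0566), GRP9 (WT 1, mutant 1 and 3, up to 0.109), ATCG00250 (WT 2, 0.0506) and ATCG00140 (WT 1, 2 and 3, up to 0.0821).

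For some genes of the early auxin list, lower in the mutant at 0 h, the genotypes differed in change over time. Tests of a region share its 0 h libraries. GH3.6 in basal segments went from 9.29 ± 0.767 to 23.1 ± 2.69 CPM in the mutant and from 32.7 ± 5.18 to 16.1 ± 6.05 CPM in WT (interaction log2 fold change 2.33 ± 0.37, adjusted p = 0.000382). Of the list in basal segments 4 of 19 had a positive interaction and 0 a negative one (7 and 0 over the list alone, camera adjusted p = 2.91e-07) at 8 h. At 16 h 6 of 19 had a positive interaction and 0 a negative one (7 and 0 over the list alone, camera adjusted p = 1.95e-06). In medial segments 4 of 19 had a positive interaction and 0 a negative one (11 and 0 over the list alone, camera adjusted p = 5.59e-06) at 8 h. There 3 of 19 had a positive interaction and 0 a negative one (4 and 0 over the list alone, camera adjusted p = 0.00366, adjusted p = 0.144 with an estimated correlation) at 16 h. RBCS1A in basal segments went from 31.8 ± 2.04 to 113 ± 24.4 CPM in the mutant and from 74.1 ± 16.1 to 35.6 ± 10.1 CPM in WT (interaction log2 fold change 2.89 ± 0.37, adjusted p = 1.28e-05). Of the photosynthesis genes 7 of 20 had a positive interaction and 0 a negative one (16 and 0 over the list alone, camera adjusted p = 1.1e-30). RGF6 had the highest interaction in basal segments at 8 h (log2 fold change 10.73 ± 1.52, adjusted p = 0.000121). Its call ended with 1 library left out (mutant 8 h 1, 1 as its adjusted p). In medial segments at 8 h the starvation gene DIN10 (4.39 ± 0.86 log2) and the wall gene XTH22 (2.96 ± 0.55) had positive and AT3G56260 (-5.36 ± 0.55) and GSTU25 (-7.05 ± 1.46) negative interactions. Upward and downward counts were 123 and 42 in basal segments at 8 h and 253 and 222 at 16 h. In medial segments they were 381 and 228 at 8 h and 401 and 489 at 16 h. The basal total of 475 at 16 h is not set against the fit without the 4 libraries, as 1 mutant library is left there. With 1 library left out basal totals lay between 108 (without WT basal 8 h replicate 1) and 178 at 8 h and between 197 (without ahk3 ahk4 basal 0 h replicate 2) and 1356 (without ahk3 ahk4 basal 16 h replicate 3) at 16 h. Medial totals lay between 301 (without ahk3 ahk4 medial 0 h replicate 3) and 833 at 8 h and between 429 (without ahk3 ahk4 medial 0 h replicate 2) and 1001 at 16 h. In a fit of the compared groups alone they were 121 in place of 609 and 1769 in place of 890.

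Whether the genotype effect differed between the regions was tested at each time. At 8 h 10 genes passed in the fit of all groups and 0 in a fit of these 12 libraries alone (edgeR, 852 at an unadjusted p under 0.05, and 38 by DESeq2 over all groups), so the 10 depend on that choice. In the fit of all groups PER64 passed, which in medial segments stood at 109 ± 27.9 CPM in the mutant against 121 ± 13.4 CPM in WT (interaction log2 fold change -2.73 ± 0.42, adjusted p = 0.000957). Negative interactions also passed for UCC1 (-2.92 ± 0.41 log2), AT2G39430 (-2.79 ± 0.47), ESB1 (-2.31 ± 0.45) and CASP1 (-2.22 ± 0.39). Of the endodermis list 0 of 14 had a positive interaction and 3 a negative one (0 and 5 over the list alone, camera adjusted p = 6.22e-13). GSTU20 was the single positive one at 8 h (log2 fold change 2.14 ± 0.42, adjusted p = 0.0218), against 9 negative. In the 12 libraries alone the folds stayed and the adjusted p was 0.0746 for UCC1, 0.191 for PER64, 0.215 for CASP1, 0.239 for AT2G39430, 0.266 for GSTU20 and 0.528 for ESB1. At 0 h 6 were positive and 41 negative, and between 13 (without ahk3 ahk4 medial 0 h replicate 2) and 73 passed with 1 library left out. The sugar transporter gene STP1 (1.85 ± 0.36 log2) was positive and RGF6 (-5.88 ± 1.02), SAUR20 (-5.49 ± 0.95) and the wall gene XTH32 (-4.23 ± 0.37) negative. At 16 h 1045 were positive and 1100 negative. PHI-1 (6.21 ± 1.57 log2) and ENODL15 (5.34 ± 1.29) were positive and the plastid gene ATCG00250 (-9.97 ± 1.87) and the transcription factor gene WRKY50 (-6.78 ± 1.88) negative. With the share of reads outside genes as a covariate 41 genes passed at 16 h. With the covariate PHI-1 (6.18 ± 1.98, adjusted p = 0.157), ENODL15 (5.6 ± 1.78, adjusted p = 0.152), ATCG00250 (-6.07 ± 1.81, adjusted p = 0.123) and WRKY50 (-9.81 ± 2.67, adjusted p = 0.0925) lost their call. The folds of all but ATCG00250 were then about as large or larger and their SE wider. Without the 4 libraries with under 2% of such reads 1 mutant basal library is left at 16 h. The interaction log2 fold changes were then 6.2 for PHI-1, 5.09 for ENODL15 and -8.57 for WRKY50. The adjusted p of ENODL15 was 0.0526 in those groups alone. Leaving out 1 replicate ended the calls of PHI-1 (WT medial 1, 0.0627) and WRKY50 (WT basal 3, mutant basal 2, up to 0.0787) at 16 h. Earlier calls ended so were ESB1 (WT basal 1 and 2, mutant basal 2 and 3, WT medial 1 and 2, mutant medial 1 and 2, up to 0.176) and GSTU20 (WT basal 1 and 3, mutant basal 1, WT medial 3, mutant medial 2, up to 0.142) at 8 h and STP1 (WT basal 2, WT medial 1, up to 0.0638) at 0 h.

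**Figure D3:**
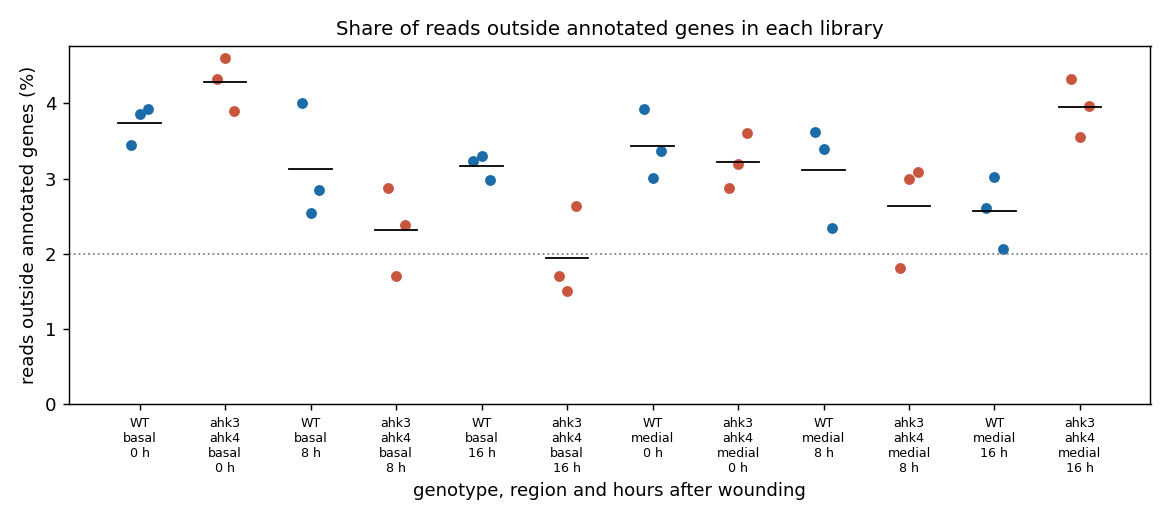
Share of reads outside annotated genes, in percent, in each of the 36 libraries by genotype, region and hours after wounding. Points are libraries (blue WT, red ahk3 ahk4), bars the group means, and the dotted line marks 2%. At 16 h the genotypes do not overlap in either region, the mutant being lower in basal and higher in medial segments. The 4 libraries below the line are all ahk3 ahk4: 2 of the basal group at 16 h, 1 of the basal group at 8 h and 1 of the medial group at 8 h.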

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

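The counts over other splits of the libraries, the covariate for reads outside genes and the fit without 4 libraries were chosen after results had been seen, and the predictions for the splits were written after their first counts.

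The genotype by region test at 16 h passed for 2145 genes, against 10 at 8 h and 47 at 0 h. Part of it may come from the share of reads outside genes, at 16 h lower in mutant basal and higher in mutant medial than in WT libraries. The same holds for organelle reads and reads aligned at more than 1 place, which were not tested. With the share as a covariate 41 genes passed, 20 of them among the 2145, of which 2026 kept their sign. Over the 2145 genes the median log2 fold change in the direction called went from 1.83 (median SE 0.48) to 0.93 (median SE 0.55). The calls therefore ended by a smaller effect and a wider SE. Priming inside transcripts at runs of A, which would lower such reads and genes together, remains open. An internal run of at least 8 A was in 30.6% of the genes with a negative and 21% of those with a positive interaction, an odds ratio of 1.2 at matched length (95% interval 0.96 to 1.49). A genotype effect that differs between the regions at 16 h also stays open. Without the 4 libraries with under 2% of such reads 1 mutant basal library is left at 16 h, so no count of calls is given for that fit. In it the median was 1.46 (median SE 0.5) and 2143 of 2145 kept their sign. At 16 h the covariate, the genotype and the other traits move together, and cannot be told apart for the genes that lost their call.

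Each interaction is listed because it tests a difference between groups directly. Other splits were refitted on its 12 libraries alone, 100 per interaction with the real one. Draws of 40 and 30 splits had been made and seen before the 100, and overlap with them. For genotype by region at 16 h the real split gave 3251 genes and the highest other 660, as large in 1 of 100. At 0 h 47 genes passed, and on those groups alone the real split gave 93 and the highest other 340, as large in 4 of 100. At 8 h 10 genes passed, but on those groups alone the real split gave 0 (edgeR, 852 genes at an unadjusted p under 0.05, and 38 by DESeq2 over all groups). The highest other gave 5. With a real count of 0 all 100 splits are as large whatever the data hold, so they decide nothing there. Genotype by time in basal segments passed for 165 genes at 8 h (real split 156, highest other 294, as large in 4 of 100) and 475 at 16 h (1257, 347 and 1 of 100). In medial segments it passed for 609 genes at 8 h (real split 121, highest other 318, as large in 2 of 100) and 890 at 16 h (1769, 554 and 1 of 100). Region by time in WT passed for 1215 genes at 8 h (real split 1111, highest other 745, as large in 1 of 100) and 2003 at 16 h (3594, 1305 and 1 of 100, with 1878 the highest other in the earlier draws). For genotype by region at 16 h and for these 6 the share of the 100 was under 0.05, so chance can be excluded, by the narrowest margin (4 of 100) for basal segments at 8 h. The first 40 splits of the medial one at 8 h, 2 of them as large, lie inside its 100. For genotype by region at 0 h 5 of the first 40, not all inside its 100, were as large (highest other 2626), and 6 of the 134 distinct splits of all draws. Chance stays open there as well. The splits with 340 and 2626 genes kept the genotype labels of 1 region and exchanged 2 or all 3 in the other. They thus carry part or all of the genotype difference.

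Pairs of groups with 3 libraries each have 10 splits, too few for a share under 0.05. Real counts fitted on the pair alone, as large in 1 of the 10 splits with no gene called in the highest other, were 8745 and 9880 for WT basal and 6969 and 7887 for WT medial segments at 8 and 16 h against 0 h. They were 7637 and 8426 for ahk3 ahk4 basal and 5124 and 7580 for ahk3 ahk4 medial segments. Between regions they were 3743, 2069 and 5779 in WT at 0, 8 and 16 h, and 2377 and 5677 in ahk3 ahk4 at 0 and 16 h. At 8 h in ahk3 ahk4 the real count was 1197 and the highest other 1. Between genotypes they were 1362, 35 and 1287 in basal segments at 0, 8 and 16 h, and 1291 and 2334 in medial segments at 0 and 16 h. In medial segments at 8 h the real count was 3 and the highest other 10, with 2 of the 10 splits as large.

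Reads outside annotated genes, which are counted for no gene, are listed for their share and reached 4.61% in ahk3 ahk4 basal replicate 2 at 0 h.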

How the results depend on the processing

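The covariate and the fit without the 4 libraries were added after the data had been seen. With RLE size factors, without the low-count filter and with the replicate block all 29 counts of genes stayed within 1.5 times their value. Counts that moved further follow, with the range when 1 compared library was left out. Parentheses hold replicates whose removal moved them that far. A fit of the compared groups alone takes the spread from those libraries, and counts both fell and rose in it. Replicate pairs differed in spread, from 9.76 (WT basal 16 h) to 99 (ahk3 ahk4 medial 8 h) chi-square per degree of freedom. The causes were not tested.

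Change in ahk3 ahk4 basal segments at 16 h went from 9303 to 5865 with the covariate and 5997 without the 4 libraries. It gave 8024 to 9004 with 1 library left out. The regions of WT at 0 h went from 2477 to 3743 in those groups alone. They gave 1677 to 1978 with 1 library left out. The regions of ahk3 ahk4 at 0 h, at 2452, gave 1548 to 2208 with 1 library left out (basal 2, medial 2). The regions of ahk3 ahk4 at 8 h went from 2622 to 1197 in those groups alone. They gave 1930 to 2529 with 1 library left out. The regions of ahk3 ahk4 at 16 h went from 5267 to 2616 with the covariate and 2197 without the 4 libraries. They gave 3608 to 5569 with 1 library left out. Genotype in basal segments at 0 h went from 610 to 928 by DESeq2, 1362 in those groups alone and 929 without the 4 libraries. It gave 342 to 465 with 1 library left out (WT 1, mutant 1 and 2). Genotype in basal segments at 8 h went from 58 to 147 by DESeq2 and 35 in those groups alone. It gave 35 to 61 with 1 library left out (WT 1 and 3, mutant 2). Genotype in basal segments at 16 h went from 982 to 1849 by DESeq2, 106 with the covariate and 42 without the 4 libraries. It gave 73 to 2412 with 1 library left out (WT 1, 2 and 3, mutant 1, 2 and 3). Genotype in medial segments at 0 h, at 1144, gave 560 to 916 with 1 library left out (WT 1, mutant 2). Genotype in medial segments at 8 h went from 448 to 1066 by DESeq2, 3 in those groups alone, 296 with the covariate and 126 without the 4 libraries. It gave 55 to 1440 with 1 library left out (WT 1, 2 and 3, mutant 1 and 3). Genotype in medial segments at 16 h went from 658 to 1328 by DESeq2, 2334 in those groups alone, 369 with the covariate and 1427 without the 4 libraries. It gave 177 to 453 with 1 library left out (WT 1 and 2, mutant 1, 2 and 3). Genotype by time in basal segments at 8 h went from 165 to 353 by DESeq2. It gave 108 to 178 with 1 library left out (WT 8 h 1). Genotype by time in basal segments at 16 h went from 475 to 978 by DESeq2, 1257 in those groups alone, 133 with the covariate and 89 without the 4 libraries. It gave 197 to 1356 with 1 library left out (WT 0 h 1, 2 and 3, mutant 0 h 1 and 2, WT 16 h 1, 2 and 3, mutant 16 h 1, 2 and 3). Genotype by time in medial segments at 8 h went from 609 to 1103 by DESeq2 and 121 in those groups alone. It gave 301 to 833 with 1 library left out (WT 0 h 2, mutant 0 h 3, WT 8 h 2). Genotype by time in medial segments at 16 h went from 890 to 1482 by DESeq2, 1769 in those groups alone and 1634 without the 4 libraries. It gave 429 to 1001 with 1 library left out (WT 0 h 1, mutant 0 h 2, WT 16 h 1 and 2, mutant 16 h 1, 2 and 3). Region by time at 16 h went from 2003 to 3594 in those groups alone. It gave 1449 to 1775 with 1 library left out. Genotype by region at 0 h went from 47 to 161 by DESeq2, 93 in those groups alone, 84 with the covariate and 92 without the 4 libraries. It gave 13 to 73 with 1 library left out (WT basal 2, mutant basal 1, 2 and 3, WT medial 1 and 3, mutant medial 2). Genotype by region at 8 h went from 10 to 38 by DESeq2, 0 in those groups alone (852 at an unadjusted p of edgeR under 0.05), 16 with the covariate and 17 without the 4 libraries. It gave 7 to 14 with 1 library left out. Genotype by region at 16 h went from 2145 to 3251 in those groups alone, 41 with the covariate and 348 without the 4 libraries. It gave 1063 to 2945 with 1 library left out (WT basal 3, mutant basal 1 and 2, mutant medial 1).

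No other count moved by more than 1.5 times. With 1 library left out, the counts against 0 h were 6744 to 7225 for WT basal 8 h, 6252 to 6511 for WT basal 16 h, 6894 to 7388 for WT medial 8 h and 6648 to 7045 for WT medial 16 h. They were 7579 to 7823 for ahk3 ahk4 basal 8 h, 6234 to 7273 for ahk3 ahk4 medial 8 h and 5841 to 6451 for ahk3 ahk4 medial 16 h. The other ranges were 2022 to 2621 for the regions of WT at 8 h, 2909 to 3381 for the regions of WT at 16 h and 817 to 1211 for region by time at 8 h.

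Of 812 tests of a list in a contrast camera called 180, 73 with an estimated correlation and 316 by fry, and 179 with the covariate. AHK3 and AHK4 passed in 10 of their 12 genotype tests, in 12 by DESeq2 and in 9 with the covariate. Each log2 fold change named in the text kept its sign under every setting. Of 193 such values 0 calls ended with RLE size factors, 3 without the filter, 13 with the covariate, 15 without the 4 libraries and 18 in a fit of the compared groups alone. With 1 library left out 75 of 1332 values lost their call. DESeq2 ended 1 of its 193 and made 3 more.

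The libraries share replicate numbers, which do not pair them. Deviations from the group means correlated at 0.009 on average for the same number and -0.005 for different numbers. Of the libraries 14 of 36 correlated best with their own number. With the replicate number as a block genotype by region at 16 h gave 2161 in place of 2145 genes. Genotype in basal segments at 16 h gave 1055 in place of 982. The lists then gave 179 calls and 1 of the named genes lost a call. Small effects are missed at the depth, spread and 3 replicates of this series: in simulated basal segments at 8 h 17 of 100 genes changed 2-fold between the genotypes were called. Depth was not varied alone.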

Other observations

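Genes of the shoot epidermis were lower in basal than in medial segments in both genotypes. In WT at 8 h ATML1, an epidermal regulator, differed by -2.44 ± 0.28 and the lipid transfer protein gene LTP1 by -2.38 ± 0.31 log2 (basal against medial). Of that list 0 of 9 were higher and 6 were lower (0 and 7 over the list alone, camera adjusted p = 1.84e-07). In ahk3 ahk4 at 8 h ATML1 differed by -2.84 ± 0.28 and FDH, a wax and cutin gene, by -1.18 ± 0.25 log2. Of the list there 0 of 9 were higher and 6 were lower (0 and 8 over the list alone, camera adjusted p = 5.44e-08). Some genes of the xylem and of sugar starvation differed between the genotypes. LAC17, a laccase of lignin formation, was lower in mutant basal segments at 8 h (log2 fold change -1.94 ± 0.41, adjusted p = 0.0159). Of the xylem list 0 of 10 were higher and 1 were lower (0 and 5 over the list alone, camera adjusted p = 5.94e-10). The starvation genes DIN10 (log2 fold change -2.88 ± 0.62, adjusted p = 0.0047) and ASN1 (-1.77 ± 0.49 log2) were lower in mutant medial segments at 0 h. Of their list 0 of 8 were higher and 2 were lower (0 and 5 over the list alone, camera adjusted p = 0.000775, adjusted p = 0.0543 with an estimated correlation). In the test of genotype by time in medial segments at 8 h DIN10 (4.39 ± 0.86 log2) and ASN1 (7.05 ± 1.64) passed. Of the list 2 of 8 had a positive interaction and 0 a negative one (5 and 0 over the list alone, camera adjusted p = 0.000172). Leaving out 1 replicate ended the calls of LAC17 (WT 3, mutant 2 and 3, up to 0.125), of ASN1 (WT 1, mutant 2 and 3, up to 0.133) at 0 h and of ASN1 (mutant 8 h 2, 0.113) in the interaction.

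The 3 tests that follow were chosen after the results they measure had been seen. Clock genes changed over time in WT segments of both regions. At 16 h GI (-4.34 ± 0.37 log2) and PRR7 (-3.81 ± 0.42) fell in basal segments. Of the list 1 of 13 rose and 8 fell (1 and 9 over the list alone, camera adjusted p = 0.00137). In medial segments LHY changed by 2.06 ± 0.30 log2 and PRR7 by -3.40 ± 0.41 log2. In the list 1 of 13 rose and 9 fell (1 and 9 over the list alone, camera adjusted p = 0.00407). Unwounded segments of the same hours are not among the groups, so part of the change over time may follow the hour of sampling and not the wound. If so, clock genes would move alike in both regions. Of these genes 9 of 13 passed the same way in basal and medial segments, and 1, GI (log2 fold change -1.56 ± 0.48, adjusted p = 0.0302), passed the region by time test, as this explanation needs. The call of GI ended without 1 of 6 libraries (basal 0 h 3, basal 16 h 1, medial 0 h 1 and 2, medial 16 h 1 and 2, up to 0.203) and in a fit of the compared groups alone (0.0529). A p that misses the threshold does not show equal changes, and the hour and the wound remain confounded for every comparison against 0 h.

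A change of light between growth and the hours after excision may also move genes over time, the labels giving low light for growth only. It was tested with 13 light-induced and 11 shade-induced genes. They were chosen from textbook knowledge after flavonoid and early light-induced genes had led the folds, without members of the fixed lists or the genes that led the folds. At 8 h the light-induced genes that rose made up 61.5% in WT basal, 46.2% in WT medial and 69.2% in both series of mutant segments. The shade-induced genes that fell made up 45.5%, 81.8%, 27.3% and 27.3% of WT basal, WT medial, mutant basal and mutant medial segments. Those that rose made up 18.2%, 9.1%, 27.3% and 9.1%, so in mutant basal segments as many rose as fell. At least 70% of each set had been set as the mark for a change of light. At most 30% of the shade-induced genes in all 4 series were the mark against it. Neither mark was met, the share of shade-induced genes ranging from 27.3% in the mutant series to 81.8% in WT medial segments, so the question stays open. Wounding itself can move such genes, and light in the hours after excision is not stated in the labels.

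Besides AHK3, 4 genes passed the same way in all 6 genotype comparisons. AT1G27565 and AT1G64795 were higher and MRD1 and AT3G01345 lower in ahk3 ahk4. Such differences may come from sequence carried along with the disrupted loci. AT1G27565 lies 32 loci from AHK3 in the order of the TAIR10.1 reference, MRD1 2095 and AT1G64795 3406 loci from it, and AT3G01345 is on another chromosome. Having 1 of 4 genes within 100 loci of AHK3 or AHK4 gave a permutation p of 0.0479 (one-sided, 100000 draws from the tested genes, 1.2% of which lie that close). This rests on 1 gene whose place had been seen before the test, so it remains open, and for the other genes the distance argues against it.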
